A study of Mus musculus with 16 samples.

How the data were processed

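Lung RNA from 4 pools of LPS-exposed mice and 4 pools of air-breathing mice (3 animals and 5 ug of RNA per pool and labelling) was labelled by reverse transcription with aminoallyl-dUTP and coupling to Cy3 or Cy5. Each of the 16 two-colour arrays paired a pool with a commercial universal mouse reference RNA, and the dyes were swapped between the 2 arrays of a pool. Groups, pool numbers and dyes were taken from the labels. The pool was the unit of replication, and the 2 arrays of a pool counted as 1 replicate.

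Each array came as a spot table with, per the file headers, integrated intensity values made with TIGR Spotfinder version 2.2.3 or 2.2.4 from the Cy3 and Cy5 images. The deposited intensity columns already had the local background subtracted and were not normalised. A second deposited table held the authors' log2 ratios of the same arrays, whose scale, centring and direction were worked out by comparison with the spot intensities. Its columns followed log2(lung/reference) with r between 0.982 and 0.998 and slopes of 0.961 to 0.997 against the loess-normalised ratios of the same spots. The exception was air pool 4 with lung in Cy3, where the slope of 0.297 showed that the authors' column was on the log10 scale (a log2 unit is 0.301 there). The column medians were, for LPS pools 1 to 4 with lung in Cy3, -0.0529, 0.0125, -0.136 and -0.129. For air pools 1 to 4 with lung in Cy3 they were -0.0186, -0.0958, 0.0514 and 0.00332. With lung in Cy5 they were -0.0448, -0.0355, 0.0471 and 0.0342 for the LPS pools and 0.059, 0.086, 0.0889 and 0.0782 for the air pools. How the authors normalised that table is not given in the sources used here.

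The deposited file of air pool 4 with lung in Cy3 combines, per the file headers, the Cy3 image of its own array with the Cy5 image of another array, the one of air pool 3 with lung in Cy5. Its Cy5 values correlated with that array at r = 0.9985, while the next highest correlation was 0.958. The file thus holds a ratio of lung to lung and not of lung to reference. The design fixed before the data were examined used all 16 arrays. Because this file holds another quantity than the design assumed, 15 arrays were used, air pool 4 was measured by its array with lung in Cy5 alone, and the fit with all 16 is given beside the leading counts. This choice was made after the data were examined, and in air pool 4 the dye effect does not cancel.

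Spots with a value of 0 or below in a channel were treated as missing. The deposited tables also hold a factor per spot (SF), not defined in the sources used here. Among spots with signal in both channels it was below 1 on 1444 spots of the version 2.2.3 arrays, 97.9% of them in the top 10% of intensity, and on 0 spots of the version 2.2.4 arrays. These spots were kept. With R 4.3.3 and limma 3.58.1, log2 ratios were normalised within each array by loess over intensity, turned to log2(lung/reference) and averaged to the pool. A feature was tested with at least 3 pools in each group, by lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Where a gene had several probes the one with the highest mean intensity was used, and probes without a symbol were kept as features of their own (4148 tested). Control spots were not told apart from these, so the test was repeated on named genes alone. The annotation gave 1 gene symbol for 18218 probes, several for 16, which were not named, and none for 4341, with 16504 different symbols. Of the probes with 1 symbol, 18175 were matched by gene number to a RefSeq table of assembly GRCm38.p6, used for names only, and 0 symbols changed. Some genes of the fixed lists are not analysed here. No coordinates are given, since no genome build goes with the files.

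The numbers of the deposited spots did not follow the annotation's feature numbers. Taken as numbered, the 2 probes of a gene correlated at r = 0.0456 over the air pools. The 8 ways of laying the feature numbers over the grid of 215 by 105 spots (axes exchanged or not, each axis turned or not) were compared on air pools only. With the axes exchanged and both turned, the correlation was 0.527 over 1030 gene pairs, against at most 0.0718 for the other 7. It was between 0.47 and 0.612 in each of 5 equal parts of the grid. Sftpc then lay at percentile 99.97 of lung over reference and the type 2 cell list at a median percentile of 98.5. This placement was used for every gene name, and all names depend on it. Between the 2 probes of a gene, the difference between LPS and air correlated at r = 0.358, and 85.5% of 62 changed genes had probes that went the same way.

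Gene lists (23, with 885 genes, 33 on more than 1 list and 789 measured) and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and falls among named genes past the threshold whose groups did not overlap, up to 3 members per list with the smallest p, and 16 genes whatever their values, giving 91 genes. It left 1 of the 16 out as not analysed here. Lists were tested with limma's camera on the moderated statistics (preset correlation 0.01, adjusted over the lists), again with an estimated correlation, and with fry. Counts "adjusted over the list alone" used the list's members only. None of the 91 genes had a net lung signal smaller than the local background on every array of a group, so no difference is given as a bound.

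The chain from intensities to calls was tested on simulated arrays with the LPS against air design and 20629 features, built from the pools' real means and spreads, with 50 tested genes changed at each size of change (49 at a size of 2). Of changes of 0.5, 1, 2 and 3 on the log2 scale, 4%, 62%, 93.9% and 100% were recovered in the right direction, and 1.53% of calls were false. A list moved by 0.4 was found (median 0.42), and 1 of the other 22 lists was called as well. The simulated noise was independent between genes and held no batch effect. These rates therefore do not cover variation that genes or pools of a batch share in the real arrays. The precision is limited by the number of arrays, and small changes were mostly missed in the simulation. Far fewer genes were changed there than the 1375 features called in the real comparison. The Benjamini-Hochberg threshold was therefore stricter in the simulation, and the shares recovered do not carry over to the real arrays.

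Alternatives fixed beforehand were median centring without loess, normexp background correction with an offset of 50, quantile scaling of intensities, the authors' table, 3 filters on features, averaging of probes, and the arrays of each dye orientation. Also fixed were a fit of separate arrays with a dye term and the pool as a random block, the pool number and the array batch as blocks, eBayes with a trend and robust setting, leaving out each pool, and the other list tests. Named genes alone, each batch alone and the omission of spots with a factor below 1 were added after the data were examined. The fit with all 16 arrays was the design fixed beforehand. It became an alternative when an array was left out of the main fit, after the data were examined. The batch is the program version: 2.2.3 for LPS pools 1 and 2 and air pools 3 and 4 (the first batch), and 2.2.4 for LPS pools 3 and 4 and air pools 1 and 2 (the second batch).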

Results

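The study asked how the mouse lung transcriptome differed at the end of repeated inhalation of lipopolysaccharide (LPS), the outer-membrane component of Gram-negative bacteria that is sensed through CD14 and TLR4. Male C57/BL6 mice aged 8 weeks inhaled aerosolised LPS for 5 days or breathed air only. Lung RNA was pooled from 3 animals, giving 4 LPS pools and 4 air pools from 24 mice. Each pool was hybridised on 2 two-colour oligonucleotide arrays of 22575 spots against a commercial mouse reference RNA, once with lung in Cy3 and once with lung in Cy5. All levels below are log2(lung/reference) per pool, and all differences are LPS minus air with their standard error (SE). The labels describe the pools as separate groups of animals, so the spread between pools holds animal-to-animal variation averaged over 3 mice.

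Signal in both channels was positive on 96.1% to 99.5% of spots per array. The median lung intensity was between 4.28 and 28.2 times the local background. The number of arrays limits the precision of every value. Of the 16 arrays, 15 entered the comparison, because the deposited file of air pool 4 with lung in Cy3 joined images of 2 different arrays. Gene names rest on a placement of the annotation on the grid of spots that was worked out from the data.

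Inhaled LPS was followed by a broad rise of inflammatory transcripts in the lung. Serum amyloid A3 (Saa3), an acute phase protein made locally in inflamed tissue, rose 105-fold, by 6.71 ± 0.55 on the log2 scale (SE, n = 4 pools per group, limma adjusted p = 0.000106). Air pool 2 lay above the other air pools for Saa3, and without it the rise was 7.33, or 161-fold. The interferon-induced T cell chemoattractant Cxcl10 rose 43.4-fold (5.44 ± 0.17), and lipocalin 2 (Lcn2), which binds bacterial siderophores, rose 23.4-fold (4.55 ± 0.55). A factor that the files give per spot, and do not define, was below 1 for Lcn2 on 3 of 15 arrays (lowest 0.527), and without these spots Lcn2 rose 27.9-fold (4.80). The cystine transporter Slc7a11 and the macrophage inflammatory protein Ccl3 also rose, but the sizes (4.54 and 4.46) are weakly determined. Their lung signal, net of background, was smaller than the local background on 3 of 7 air arrays for Slc7a11 and on 4 of 7 for Ccl3. That of Cxcl10 in air was a median of 1.32 times the local background, so its fold is weakly determined as well. The falls were smaller: the largest among genes whose groups did not overlap was that of paraoxonase 1 (Pon1), a lipid-peroxide hydrolase, at 3.69-fold lower (-1.88 ± 0.35, adjusted p = 0.0114).

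Of 20629 features tested with limma, 1375 differed at a Benjamini-Hochberg adjusted p under 0.05. Of these, 1228 were higher and 147 lower in LPS. The counts depend on pools and scaling: fits without 1 pool gave 711 to 1262 changed and 45 to 162 lower, and median centring in place of loess gave 735 changed and 49 lower. A rise above 2-fold was found for 471 of them and above 4-fold for 79, whereas 23 fell by more than 2-fold and 0 by more than 4-fold. Among the 16481 features with a gene symbol, 1103 rose and 124 fell. The 4 LPS pools lay on one side of all 4 air pools for 1364 of the 1375 features. Over features with a value in every pool, 16.7% had groups that did not overlap, against 2.86% by chance. With all 16 arrays, as the design was fixed before the data were examined, 501 features differed, 476 higher and 25 lower.

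The arrays fell into 2 batches by the version of the image-analysis program, each with 2 pools of each group. With the batch as a block, 2265 features differed (1798 higher, 467 lower) and all 1375 features of the unblocked comparison were among them. Fitted on the 4 pools of version 2.2.3 alone, 4707 features differed (3003 higher, 1704 lower). The 4 pools of version 2.2.4 alone gave 1158 (902 higher, 256 lower). Across spots, the 2 arrays of a pool agreed less in version 2.2.4 (r = 0.418 to 0.795) than in the complete pools of version 2.2.3 (0.82 to 0.899). The names of the scanned images carried the number of a week, which was 1 for all LPS arrays, 4 for air pools 1 and 2 and 8 for air pools 3 and 4, while the labels name 1 week of exposure. What that number stands for is not given in the sources used here. The week number separates all LPS arrays from all air arrays, so in every difference given here it cannot be told apart from the exposure. Among the air pools the week number and the batch coincide, so a difference between batches that lies in the air pools cannot be assigned to either.

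Among the other genes of the 12 largest rises, orosomucoid 1 (Orm1), an acute phase plasma protein, rose by 4.44 ± 0.57 (3.55 and 5.33 within the batches) and the interleukin-1 receptor antagonist Il1rn by 4.20 ± 0.36. Timp1, an inhibitor of matrix metalloproteinases, rose by 4.03 ± 0.17. The remaining members of the 12 largest rises were Slfn3 (3.84 ± 0.34, with 4.63 and 3.05 within the batches), the chemokine Cxcl9 (3.83 ± 0.22), the formyl peptide receptor Fpr2 (3.67 ± 0.29) and the metalloreductase Steap4 (3.46 ± 0.41). Their adjusted p-values lay between 1.99e-07 for Cxcl10 and 0.00133 for Orm1. For Cxcl9 the net lung signal in air was a median of 1.44 times the local background, and smaller than it on 1 of 7 air arrays.

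**Figure D1:**
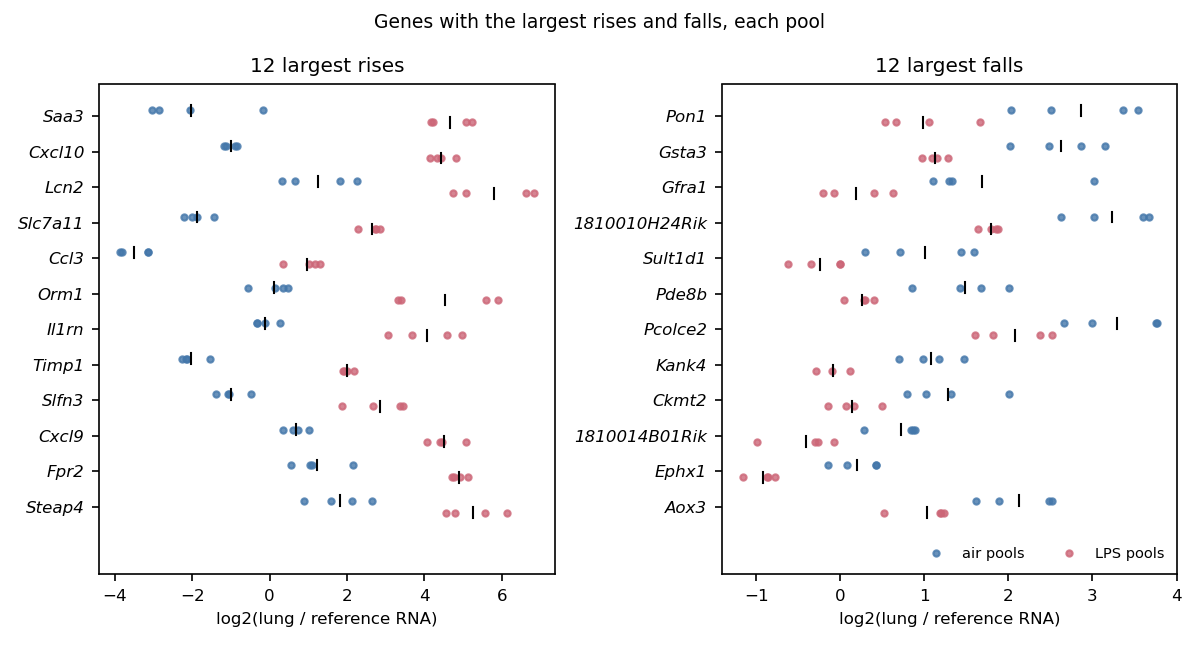
Levels of the 12 genes with the largest rises (left) and the 12 with the largest falls (right) among named genes that passed the test and whose groups did not overlap. Each point is 1 pool, its position the log2(lung/reference RNA), with air pools in blue and LPS pools in red and a black bar at each group's mean. Saa3 averaged -2.04 in the air pools and 4.67 in the LPS pools.

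Acute phase and antimicrobial genes contained the largest rise, that of Saa3. Of 26 measured members of the list fixed beforehand, 15 were higher in LPS, 0 were lower and 11 did not pass (19 higher when adjusted over the list alone). Besides Saa3, Lcn2 and Orm1 these included Orm2 (2.91 ± 0.24, with 2.53 and 3.30 within the batches) and the metal-binding metallothioneins Mt1 (2.14 ± 0.16) and Mt2 (2.86 ± 0.29). The list's median difference was 1.62 (camera adjusted p = 3.16e-23), 1.62 with the batch as a block, 1.32 in the pools of version 2.2.3 and 1.70 in those of version 2.2.4. The call was lost with an estimated correlation between genes (adjusted p = 0.0782). Camera p-values with the preset correlation, here and below, may be too small. Splits of the pools with 2 LPS pools in each group still gave up to 10 lists past the threshold.

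Chemokines, the attractants of leukocytes, also rose as a group, with 16 of 35 members higher, 0 lower and 19 not passing (20 higher when adjusted over the list alone). Ccl9 rose by 2.96 ± 0.16 and Cxcl2, a neutrophil attractant, by 3.04 ± 0.49 (1.73 in the first batch and 4.35 in the second, adjusted p of the difference 0.0236, limma). Cxcl1, another neutrophil attractant, differed by 0.02 ± 0.57 (adjusted p = 0.986), with an SD of 1.40 between the air pools. The list's median difference was 0.88 (camera adjusted p = 9.31e-29; 0.0296 with an estimated correlation). It was 0.88 with the batch as a block, 0.95 in the first batch and 0.83 in the second.

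Of 55 genes of LPS sensing, NF-kB signalling and cytokines, 24 were higher, 0 lower and 31 did not pass (31 higher when adjusted over the list alone). Interleukin-1 beta (Il1b) rose by 3.45 ± 0.26, the prostaglandin E synthase Ptges by 2.02 ± 0.14, tumour necrosis factor (Tnf) by 1.56 ± 0.22 and the LPS co-receptor Cd14 by 1.84 ± 0.17. Tlr4, the LPS receptor itself, differed by 0.25 ± 0.20 (adjusted p = 0.473). The list's median was 0.68 (camera adjusted p = 3.16e-23; 0.0361 with an estimated correlation), 0.68 with the batch as a block, and 0.65 and 0.69 within the batches.

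Interferon-stimulated genes rose in 24 of 44 members, 0 fell and 20 did not pass (31 higher when adjusted over the list alone). The antiviral gene Rsad2 rose by 2.80 ± 0.16, Ifi205 by 2.52 ± 0.18 and the guanylate-binding protein Gbp4 by 2.21 ± 0.17. The median was 0.97 (camera adjusted p = 6.45e-31; 0.0296 with an estimated correlation), 0.97 with the batch as a block, and 0.94 and 0.97 within the batches. Among genes of major histocompatibility complex (MHC) molecules and antigen presentation, 13 of 29 rose, 0 fell and 16 did not pass (18 higher when adjusted over the list alone). Examples were the lysosomal protease cathepsin S (Ctss, 2.06 ± 0.21), the peptide transporter Tap1 (1.75 ± 0.19) and the immunoproteasome subunit Psmb8 (1.43 ± 0.17). This list's median was 0.77 (camera adjusted p = 1.28e-12), 0.77 with the batch as a block, and 0.73 and 0.75 within the batches. Its call was lost with an estimated correlation (adjusted p = 0.0556).

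Markers of 2 kinds of phagocyte were higher in LPS lungs. Of 45 macrophage and monocyte markers, 26 were higher, 0 lower and 19 did not pass (30 higher when adjusted over the list alone). The Fc receptor chain Fcer1g rose by 3.03 ± 0.19, the Fc receptor Fcgr2b by 2.24 ± 0.16 and the lysosomal membrane protein Cd63 by 1.37 ± 0.11. The median was 1.05 (camera adjusted p = 4.9e-33; call lost with an estimated correlation, adjusted p = 0.0556), 1.05 with the batch as a block, and 1.04 and 1.11 within the batches. Of 35 neutrophil markers, 17 were higher, 1 was lower and 17 did not pass (19 higher and 2 lower when adjusted over the list alone). The lectin Clec4d rose by 3.28 ± 0.28 and the oxidase subunit Cybb rose 2.83-fold (adjusted p = 0.000159). S100a8, a subunit of the neutrophil protein calprotectin, rose by 3.35 ± 0.77 (adjusted p = 0.0297). Its rise was 4.70 in the first batch and smaller in the second (difference -2.70, adjusted p = 0.0244), and in the 8 fits without 1 pool it lay between 2.74 and 4.01, with the call lost in 6. The median of this list was 0.75 (camera adjusted p = 2.16e-14; call lost with an estimated correlation, adjusted p = 0.0556), 0.75 with the batch as a block, and 0.52 and 0.97 within the batches.

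Lymphocyte markers showed no shift as a group. None of 34 T and NK cell markers passed the test over all features, and 0 did when adjusted over the list alone, with Ctla4 at 0.69 ± 0.21 (adjusted p = 0.0819). In that list 1 of the 3 members with the smallest p, Tbx21, was at -0.48 ± 0.18 (adjusted p = 0.151). The median was 0.04 (camera adjusted p = 0.596, direction lower, opposite to the median). Of 22 B and plasma cell markers, Fcer2a (1.03 ± 0.16) and Cd72 (1.42 ± 0.33) were higher, Tnfrsf13c was lower (-0.56 ± 0.14) and 19 did not pass. When adjusted over the list alone, 2 were higher and 3 lower. The median was -0.08 (camera adjusted p = 0.27) and the mean 0.00089, opposite in sign to the median.

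Extracellular matrix genes and proteases with their inhibitors shifted upward. In the matrix list, 10 of 55 rose, 0 fell and 45 did not pass (11 higher when adjusted over the list alone). Fibronectin (Fn1) rose by 2.03 ± 0.19, type III collagen (Col3a1) by 1.90 ± 0.17 and Col5a2 by 1.43 ± 0.15, while elastin (Eln) differed by 0.10 ± 0.22 (adjusted p = 0.833). The matrix list's median was 0.27 (camera adjusted p = 9.01e-05), 0.27 with the batch as a block, and 0.31 and 0.13 within the batches. Its call was lost with an estimated correlation (adjusted p = 0.11). Of 53 proteases and inhibitors, 11 rose, 1 fell and 41 did not pass (19 higher and 1 lower when adjusted over the list alone). Macrophage elastase (Mmp12) rose by 3.08 ± 0.21, with 3 air pools measured and its net lung signal smaller than the local background on 3 of 7 air arrays. The gelatinase Mmp9 differed by -0.26 ± 0.25 (adjusted p = 0.575). This list's median was 0.27 (camera adjusted p = 4.43e-06; 0.0361 with an estimated correlation), 0.27 with the batch as a block, and 0.38 and 0.27 within the batches.

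Apoptosis genes rose in 16 of 53 members, 0 fell and 37 did not pass (19 higher when adjusted over the list alone). The members with the smallest p were the TNF receptor Tnfrsf1b (1.29 ± 0.15), the inflammatory caspase Casp4 (0.99 ± 0.14) and cytochrome c (Cycs, 1.23 ± 0.20, with 0.62 for its other probe). The first binds TNF, Casp4 senses intracellular LPS and Cycs also serves respiration, so these members have roles outside cell death. The median was 0.14 (camera adjusted p = 0.00131; 0.0361 with an estimated correlation), 0.14 with the batch as a block, and 0.25 and 0.14 within the batches. In the first batch alone the list did not pass (adjusted p = 0.0599). Of 65 cell cycle genes, 9 rose, 0 fell and 56 did not pass (9 higher when adjusted over the list alone). Among the 9 were Kif23 (1.33 ± 0.17, with 0.52 for its other probe), the mitotic kinase Cdk1 (1.57 ± 0.20) and Mad2l1 (1.17 ± 0.17). The net lung signal of Kif23 was smaller than the local background on 1 of 7 air arrays. The cell cycle list as a whole did not pass (median 0.17, camera adjusted p = 0.0563), but did with the batch as a block (adjusted p = 0.0335). Its median was 0.22 and 0.13 within the batches.

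Genes of antioxidant defence and detoxification changed in both directions. Of 47 measured members, 11 were higher, 7 were lower and 29 did not pass (13 higher and 11 lower when adjusted over the list alone). The risers included Slc7a11, the metallothioneins and glutathione reductase (Gsr, 1.53 ± 0.13, with 0.91 for its other probe). The fallers included the glutathione transferase Gsta3 (-1.51 ± 0.22), the microsomal epoxide hydrolase Ephx1 (-1.11 ± 0.17) and the aldehyde oxidase Aox3 (-1.09 ± 0.24), which act on foreign compounds. The list did not shift as a whole: the median was -0.03, the mean 0.12 and the direction of the test upward (camera adjusted p = 0.191). Within the batches the median was -0.09 and -0.08.

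The remaining genes among the 12 largest falls were not on the antioxidant and detoxification list. They were the neurotrophic factor receptor Gfra1 (-1.50 ± 0.39), the uncharacterised 1810010H24Rik (-1.44 ± 0.22, with -0.95 and -1.92 within the batches) and 1810014B01Rik (-1.13 ± 0.22), the sulfotransferase Sult1d1 (-1.25 ± 0.28) and the phosphodiesterase Pde8b (-1.23 ± 0.22). The others were Pcolce2, an enhancer of collagen processing (-1.21 ± 0.29), Kank4 (-1.17 ± 0.20, with 3 LPS pools measured) and the mitochondrial creatine kinase of muscle, Ckmt2 (-1.14 ± 0.25). Their adjusted p-values lay between 0.00416 and 0.0469, and the net lung signal was smaller than the local background on 2 of 8 LPS arrays for Sult1d1 and for Kank4.

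Resident cell types of the lung gave few changed markers. Of 31 alveolar type 2 cell and surfactant genes, 3 were higher and 28 did not pass (3 higher when adjusted over the list alone). The alarmin Il33 rose by 1.56 ± 0.21, Dram1 by 1.20 ± 0.25 and Hc by 1.09 ± 0.27. Surfactant protein C (Sftpc), the main product of type 2 cells, differed by 0.67 ± 0.47 (adjusted p = 0.425), with -0.36 and 1.71 within the batches. The factor per spot was below 1 for Sftpc on 7 of the 8 arrays of the first batch (lowest 0.13) and on 0 of the second. Without these spots Sftpc had too few pools to be tested. The type 2 list did not pass (median 0.18, camera adjusted p = 0.315) but did with the batch as a block (adjusted p = 0.0459), and its median was 0.09 and 0.26 within the batches. Of 24 type 1 cell markers podoplanin (Pdpn) rose by 1.34 ± 0.17 and 23 did not pass (1 higher when adjusted over the list alone; median 0.15, camera adjusted p = 0.407). Of 30 airway cell markers, 3 rose and 27 did not pass (3 higher and 2 lower when adjusted over the list alone; median -0.14, camera adjusted p = 0.243). The 3 were lactoferrin (Ltf, 1.62 ± 0.25), which is also on the neutrophil list, Cd24a (0.82 ± 0.14) and the immunoglobulin transporter Pigr (2.26 ± 0.56). Of 39 endothelial markers, Icam2 was higher (1.09 ± 0.26), Esm1 lower (-0.81 ± 0.16) and 37 did not pass (1 higher and 1 lower when adjusted over the list alone). That list's median was -0.13 (camera adjusted p = 0.1; 0.041 with the batch as a block).

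Among markers of tissue that can accompany a lung sample, heart and smooth muscle genes had a median of -0.13 (camera adjusted p = 0.0281; call lost with an estimated correlation, adjusted p = 0.456), with 2 of 30 higher, 4 lower and 24 not passing (3 higher and 5 lower when adjusted over the list alone). Besides Ckmt2, smoothelin (Smtn) fell (-0.49 ± 0.11) and the smooth muscle actin Actg2 rose (0.81 ± 0.18). The muscle median was -0.13 with the batch as a block, and -0.11 and -0.24 within the batches. Red blood cell genes had a median of -0.18 (camera adjusted p = 0.0222; call lost with an estimated correlation, adjusted p = 0.0556), with 0 of 15 members passing singly over all features or when adjusted over the list alone. Alas2, the haem synthesis enzyme of erythroid cells, was at -0.85 ± 0.25 (adjusted p = 0.0794). The red cell median was -0.18 with the batch as a block, and -0.28 and -0.18 within the batches. Of 19 fat tissue genes, Lpl was higher (0.83 ± 0.21), Adig lower (-0.65 ± 0.13) and 17 did not pass (2 higher and 4 lower when adjusted over the list alone; median -0.07, camera adjusted p = 0.0995).

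Clock and glucocorticoid-responsive genes were tested because both respond to stress and handling. Of 17 clock genes, Bhlhe40 (1.24 ± 0.12) and Nfil3 (1.03 ± 0.24) were higher, Per1 was lower (-0.64 ± 0.14) and 14 did not pass (2 higher and 2 lower when adjusted over the list alone; median -0.03, camera adjusted p = 0.407). Of 20 glucocorticoid-induced genes, 4 were higher, 2 lower and 14 did not pass (6 higher and 2 lower when adjusted over the list alone), with Sgk1 at 1.31 ± 0.23. Its other 2 members with the smallest p, Lcn2 and Mt2, are also on the acute phase list. The glucocorticoid list's median was 0.08 (camera adjusted p = 0.1), 0.08 with the batch as a block (adjusted p = 0.00203), and 0.59 and -0.17 within the batches.

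**Figure D2:**
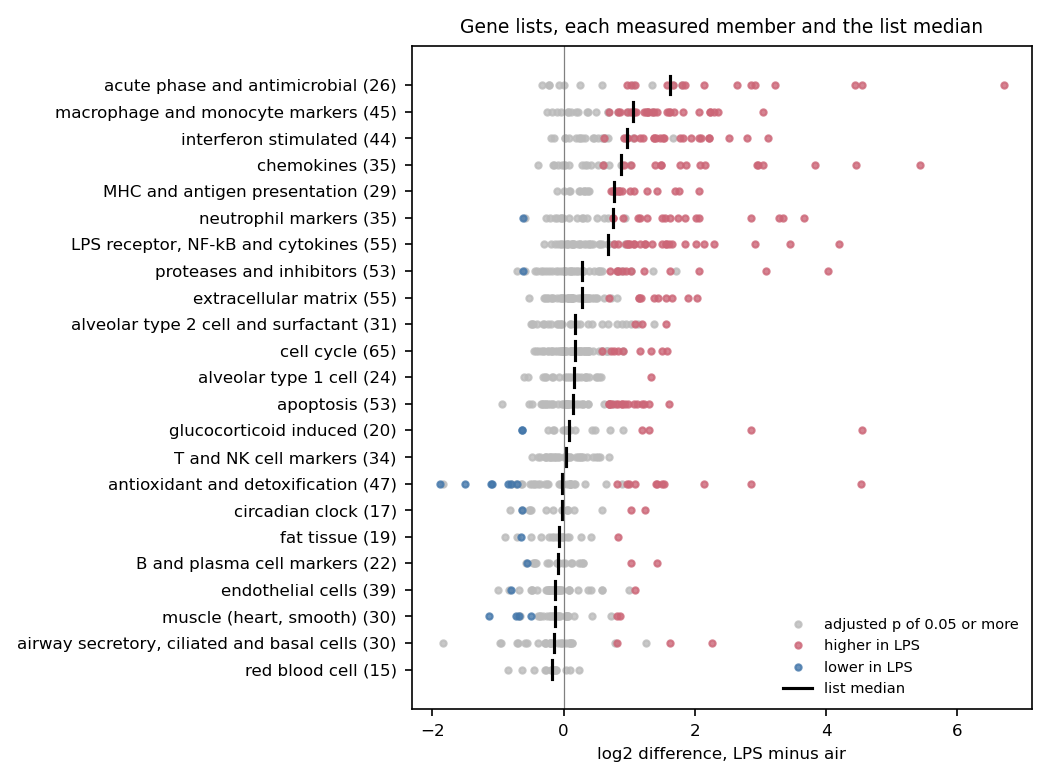
Differences in log2 level (LPS minus air) for the 23 gene lists, with the number of measured members in brackets. Each point is 1 gene, red where higher and blue where lower at an adjusted p under 0.05 and grey otherwise, and the black bar is the list's median. The median was highest for acute phase and antimicrobial genes, at 1.62, and lowest for red blood cell genes, at -0.18.

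Of the 76 genes named here that passed, 59 did so in every fit without 1 pool in which they were tested and 17 did not. The 17 were Gfra1, Sult1d1, Pcolce2, Ckmt2, Aox3, Cd72, Tnfrsf13c, Dram1, Hc, Pigr, Icam2, Actg2, Smtn, Lpl, Per1, Nfil3 and S100a8.

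Of the 23 lists, 12 passed the camera test with its preset correlation, 10 upward and 2 downward. With an estimated correlation, 5 passed: chemokines, LPS sensing and cytokines, interferon-stimulated genes, proteases and apoptosis. The rotation test fry, which tests each list by itself, called 11. After turning the dye swaps to the same direction, the 2 arrays of a pool correlated across spots with r between 0.418 and 0.899 in the 7 pools with both arrays (median 0.795; LPS pool 3 was lowest). Between pools, r was 0.752 to 0.927 among LPS pools, 0.724 to 0.934 among air pools and 0.451 to 0.812 between groups, across genes that are not independent replicates.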

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

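The tests of the array batch by the correlation between batches, of the splits that keep the batches, of each list's median over the splits, of the week numbers in the image names, of both explanations for the array of air pool 4, and of batch and clock phase for the clock genes were chosen only after the result was seen.

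The rise of 1228 and the fall of 147 of the 1375 changed features were set against all 35 splits of the 8 pools into 4 and 4. Only 1 split, the real one, gave as many changed features (highest other 351, the split by batch). The same held for the larger direction (highest other 254) and the smaller direction (highest other 97). Chance was thus unlikely for these counts over all splits but not excluded, since 1 of 35 is the smallest share they can give. The 3 counts come from the same split, and these splits do not keep the batches. The 18 splits that put 2 pools of each batch in each group are too few for a share under 0.05; among them the real one gave 2265 with the batch as a block, and the highest other 0. Chance was not excluded for the number of lists past the threshold, 12. Under the preset correlation 11 of the 35 splits, the real one among them, gave as many (highest other 17). The others of these put 1 or 3 LPS pools in a group and kept part of the LPS difference, so this count cannot decide. Splits with 2 LPS pools in each group, in which the LPS difference is balanced, still gave up to 10. The camera p-values with the preset correlation may therefore be too small. List by list, the real split alone gave the largest median for 10 of the 12, such as acute phase genes (1.62, highest other 1.16) and interferon-stimulated genes (0.97, highest other 0.65), but 4 of the 35 splits gave as large a median for apoptosis and 8 for muscle.

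An offset of the array batch was argued against as the source of the changed features by the design. Each batch held 2 pools of each group, so such an offset cancels. The differences between LPS and air in the 2 batches, which share no pool, correlated over features at r = 0.393 (highest other split that keeps the batches 0.161). This shows that they recurred in part, and is no further test of such an offset. The estimated effect still differed between the batches in 1792 features, 141 of the changed ones among them. In 1 model with both batches 675 features were called in both in the same direction, 5862 in the first alone and 297 in the second alone. The 2 arrays of a pool agreed less in the second batch (r = 0.418 to 0.795) than in the complete pools of the first (0.82 to 0.899). A difference in effect thus cannot be told apart from one in array quality. The meaning of the week numbers stayed open: 0 air arrays carry the number of the LPS arrays, so week number and exposure cannot be told apart.

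The array of air pool 4 with lung in Cy3 had a median correlation of 0.163 with the other arrays. The medians of the other air arrays lay between 0.539 and 0.692. The Cy5 channel of the air pool 4 array correlated at 0.9985 with that of air pool 3 with lung in Cy5. This lay above the highest value between any 2 other arrays (0.991), as the same Cy5 image in both files would give. Its Cy3 channel correlated at up to 0.919 with the Cy3 lung channel of another air array, where the lowest among the others was 0.776. This argues against a channel without signal. The same channel correlated at 0.939 with a Cy3 channel that held LPS lung or reference RNA. Such correlations therefore cannot show whether the lung signal is sound. No biological explanation was tested, since the design gives no group for it.

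S100a8, Cxcl2 and Sftpc had the largest differences between the batches (second minus first) among the named genes with a tested difference. Among the air pools the batch coincides with the week number in the image names, so the 2 cannot be told apart for a difference carried by the air pools. The rise of the calprotectin subunit S100a8 was smaller in the second batch than the 4.70 of the first (difference -2.70), where air pools 1 and 2 already stood at 3.61 and 4.24 and air pools 3 and 4 at 0.44 and 0.83. The rise of Cxcl2 was larger there, 4.35 against 1.73 (difference 2.62), and Sftpc differed by 1.71 against -0.36 (difference 2.07), where the spot factor was below 1 for Sftpc on 7 of the 8 arrays of the first batch and on 0 of the second. Among acute phase genes the rises of Orm1 (difference 1.78) and Orm2 (difference 0.77) were larger in the second batch. The rise of Slfn3, which is on none of the lists, was smaller in the second batch (difference -1.58). The fall of 1810010H24Rik was deeper there (difference -0.97), while Lmo7 and Tbx21 did not pass over all pools. Lmo7 was at 0.10 in the first batch and -1.20 in the second (difference -1.30), and Tbx21 at -0.89 and -0.07 (difference 0.82).

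Gene by gene, the difference between the batches (second minus first) had a median of 0.28 over acute phase genes and 0.22 over neutrophil markers, both with the larger rise in the second batch. Most of the 141 changed features whose effect differed between the batches went the other way, since only 20 of them had the larger change in the second batch. Over glucocorticoid-induced genes it had a median of -0.70.

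Single pools stood apart from the other 3 of their group for 11 gene and group pairs. With the array of air pool 4 this made 12 of 182 groups tested, where chance gives about 1 in 20, or 9.1. In air, Timp1 was at -1.55 in pool 2 (others -2.26 to -2.15), Gfra1 at 3.02 in pool 2 (1.11 to 1.33) and 1810014B01Rik at 0.28 in pool 3 (0.84 to 0.89). LPS pool 4 was low for Aox3 at 0.52 (others 1.19 to 1.23), Ptges at 0.54 (0.84 to 0.87), Gsr at 0.32 (0.50 to 0.51) and Cd14 at 1.36 (1.96 to 2.04). The same pool was high for Cd63 at 0.18 (0.07 to 0.08) and Cd72 at 2.02 (0.27 to 0.54). LPS pool 1 was low for Gbp4 at 3.12 (3.53 to 3.62) and high for Ctla4 at 0.10 (-0.65 to -0.56).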

How the results depend on the processing

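The tests with named genes alone, with each batch alone and without spots of a factor below 1 were chosen only after the result was seen. The fit with all 16 arrays follows the design fixed beforehand. Leaving an array out of the main fit was chosen after the data were examined. No call reversed its direction under the alternatives run. Chemokines, LPS sensing and cytokines, interferon-stimulated genes and proteases kept their direction and call under every alternative. Without the spots of a factor below 1, 1375 features changed and all 76 named genes that had passed did so again, but Sftpc had too few pools to be tested. Of these 76 genes, 76 kept their call with the batch as a block, 73 with the authors' table, 62 with normexp correction, 61 with median centring, 49 with all 16 arrays and 48 with the arrays of lung in Cy3 alone (of 75 tested there).

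Of the counts, 735 features changed with median centring (686 higher, 49 lower) and 416 with arrays of lung in Cy3 alone (401 higher, 15 lower), a fit with 3 air pools. With all 16 arrays 501 changed (476 higher, 25 lower), and this includes the file of 2 joined images. The array batch as a block gave 2265 changed and 467 lower, batch 2.2.3 alone 4707 (3003 higher, 1704 lower), batch 2.2.4 alone 256 lower, and arrays as separate values with the pool as a random block 309 lower. The cause of these shifts was not tested. The remaining settings, apart from the pool number as a block, gave between 1034 (lung in Cy5 alone) and 1875 changed features (random block), with 1168 in the authors' table.

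Leaving out 1 pool gave 711 to 1262 changed features, 666 to 1152 higher and 45 to 162 lower. The count moved most without LPS pool 1 (711), LPS pool 2 (752), air pool 4 (766) and LPS pool 3 (829). Without LPS pool 4, 90 were lower.

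The numbers of the pools did not pair them: the correlation between LPS and air pools of the same number was -0.263 to -0.0374, 0 of 4 were closest to their own number, and same numbers lie in different batches. With the pool number as a block 857 features changed (795 higher, 62 lower).

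Among lists, cell cycle genes passed with median centring (median 0.17), lung in Cy3 alone (0.23), the batch as a block (0.17) and without air pool 3, air pool 4, LPS pool 3 or LPS pool 4 (0.0653 to 0.2842 over the 8 fits without 1 pool). Endothelial genes passed with lung in Cy5 alone (-0.29), the batch block (-0.13) and without air pool 3, LPS pool 3 or LPS pool 4 (-0.2773 to -0.0165 over the 8 fits). Glucocorticoid-induced genes passed with lung in Cy5 alone (0.11), the batch block (0.0828), all 16 arrays (0.0934), batch 2.2.3 alone (0.83) and without air pool 1, air pool 2 or LPS pool 4 (-0.0538 to 0.292). Type 2 cell genes passed with the batch block (0.18), all 16 arrays (0.20) and batch 2.2.4 alone (0.26). Fat genes passed in batch 2.2.4 alone (-0.15) and without air pool 3 (-0.172 to 0.000184 over the 8 fits), clock genes in batch 2.2.4 alone (-0.44), airway genes without air pool 3 (-0.21 to -0.0574) and antioxidant genes without air pool 2 (-0.166 to 0.0458). Muscle genes did not pass with lung in Cy5 alone (-0.0782), in batch 2.2.3 alone (-0.11), without air pool 1, air pool 2 or LPS pool 2 (-0.191 to -0.0687 over the 8 fits), or with an estimated correlation or fry (-0.13 each). Red cell genes did not pass in batch 2.2.3 alone (-0.28) or with an estimated correlation (-0.18), nor apoptosis genes in batch 2.2.3 alone (0.25). With an estimated correlation the unchanged medians of acute phase (1.62), MHC (0.77), neutrophil (0.75), macrophage (1.05) and matrix genes (0.27) no longer passed. The cause of these differences was not tested.

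The median correlation between dye swaps was 0.795, and 0.492 with median centring and 0.469 with normexp correction. Lung signal of 4.28 times the background at the lowest limits genes near the background, such as Ccl3 in air.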

Other observations

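The tests of gene families and of the clock genes in this part, apart from that of a failed array, were chosen only after the result was seen. Some genes of the proteasome, the protease complex that degrades ubiquitin-tagged proteins, rose in LPS. Of 14 measured genes named Psmd, none of them on the lists fixed beforehand, 6 rose, 0 fell and 8 did not pass. Among them Psmd1 was at 0.82 ± 0.13 and Psmd10 at 0.93 ± 0.15 (SE, limma). The family's median was 0.39, between 0.29 and 0.58 under other scalings and 0.49 and 0.36 within the batches. Of 24 proteasome genes named Psma, Psmb or Psmc, 8 rose and 0 fell, with Psma4 at 1.02 ± 0.16 and a median of 0.37. Psmb8, one of the 8, is also on the MHC list, as are Psmb9 and Psmb10, which did not pass.

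Subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, rose in 6 of 23 measured genes and fell in 0, with Atp6v1e1 at 0.99 ± 0.15, Atp6ap2 at 0.96 ± 0.14 and a median of 0.34 (0.45 and 0.19 within the batches). Atp6v0d2, one of the 6, is also on the macrophage list. Of 23 C-type lectin genes (Clec), receptors for microbial sugars among them, 7 rose. Of these, 4 are on the fixed lists of phagocyte markers (Clec4d, Clec4e, Clec7a and Clec4n), and Clec5a (1.82 ± 0.24) is on none. The lectin median of 0.02 changed sign under other scalings (-0.03 to 0.05). Psmd and Clec came from a scan of 193 families of at least 10 symbols, in which 6 held more risers than expected by the exact hypergeometric test and 0 more fallers. After adjustment over families, p was 0.00805 for Psmd, 0.0216 for Clec and 0.0421 for all 75 Atp genes, and the other 3 families were Ccl, Cxcl and Ifi. The hypergeometric test takes genes as independent and does not allow for correlation within a family, so these p-values may be too small. The group of Psma, Psmb and Psmc genes and that of the vacuolar ATPase were put together after the scan, in which Psmb alone did not pass (adjusted p = 0.441).

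The clock gene Arntl differed between pools of 1 group: air pools 1 to 4 stood at -1.44, -1.56, 0.09 and -1.48 and LPS pools 1 to 4 at -0.79, -1.34, -0.02 and 0.09. The 2 arrays of a pool differed in Arntl by up to 1.48 (LPS pool 2; 0.951 in air pool 3, median 0.359). Air pools 3 and 4 share a batch and differed by 1.57, and by 1.09 on the arrays with lung in Cy5 alone. Against that spread these values exclude neither the array batch nor 1 failed array. Arntl ran against the mean of 11 clock output genes over the 8 pools (Pearson r = -0.838, two-sided exact permutation p = 0.00905, Spearman rho = -0.857, exact p = 0.0107, both 0.0107 after adjustment over 2 relations). Without the 2 pools farthest from the median r was -0.765. The 11 genes were Dbp, Tef, Hlf, Per1, Per2, Per3, Nr1d1, Nr1d2, Bhlhe41, Cry2 and Usp2, a choice among the clock genes. Bhlhe40, also on the clock list, was not among them and hardly differed between the air pools (SD 0.023). Batches of 4 pools were too few for a correlation of their own. Further tests, chosen after this relation was seen and not adjusted, kept part of the design. With pools exchanged only within a batch, the exact permutation p was 0.0399 for Pearson and 0.0382 for Spearman, and only within a group 0.0243 and 0.0677. With both kept, 6 of the 16 arrangements were as large by Pearson and 7 by Spearman (too few arrangements for p under 0.05), and in the second batch the pattern coincides with air against LPS. The array batch, 1 failed array and a different clock phase of the lungs at collection all stay open, and the LPS against air difference of Arntl did not pass (limma adjusted p = 0.432).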
